A study of Mus musculus with 17 samples.

How the data were processed

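RNA was measured in 17 libraries of mouse bone marrow cells that carried the cKit receptor, a mark of haematopoietic stem and progenitor cells, and lacked lymphoid and erythroid surface markers. Per the labels, cells were sorted by flow cytometry, RNA was purified on small columns, and polyadenylated RNA was made into libraries by a low-input method. The labels gave each library a genotype and a disease state. Nothing in the labels says that each library came from a separate mouse. The p-values of single genes below therefore measure the spread between these libraries. Sex, age and batch were not given per library.

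The deposited table held raw counts from the authors, 1 column per library, with no normalization. Per the submitters' processing notes the reads were aligned with STAR to mouse genome GRCm38; the version, the gene annotation, the counting tool and the strand setting were not given in the sources used here. The table held 96004 features, of which 47643 were Ensembl genes. A further 42055 were named by a gene identifier followed by enh and 6306 by enh alone; their coordinates and meaning were not given, so they were left out of the comparisons of genes and are described at the end. Genes were matched to symbols and coordinates through the GENCODE vM21 annotation of GRCm38, which may not be the release the authors used; 47224 identifiers matched without their version and 39106 with the same version. Genes that share sequence with relatives (Csf2rb with Csf2rb2, S100a8 with S100a9, Xlr4a with Xlr4b, and the H2 genes among themselves) or that overlap an antisense transcript have less certain counts, since multiple mapping and strand were handled in ways not stated.

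Counts over genes came to 21.1 to 38.3 M per library, with a median of 32.2 M. Intervals of counting are narrow at this depth for all but the rarest genes, and the errors given are the spread between libraries. Levels are CPM, counts scaled to a library of 1 M, after trimmed-mean (TMM) scaling, given as mean ± SD with n libraries. Log2 fold changes are given ± an approximate standard error (SE). It is the size of the change over the square root of the F statistic of its test.

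Choices of groups, tests, 24 gene lists and most alternatives were fixed before the data were examined. Genes with enough counts for their group size (filterByExpr, minimum count 10, minimum total 15) numbered 19951. They were tested with edgeR 4.0.16 (quasi-likelihood F test with robust spread, R 4.3.3), with 1 mean for each of the 6 genotype groups over all 17 libraries, and p-values were adjusted by Benjamini-Hochberg within each of 13 comparisons at 0.05. All p-values are two-sided. Because 1 group had 2 libraries, the spread was shared by all groups. The contrast of AML with Normal set the mean of the 2 compound groups against the mean of the 4 others, on the log2 scale. Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 24 lists. They were tested again with the correlation estimated from the data, and with fry. Camera compares the members of a list with the other genes, so its p-values do not measure the spread between libraries alone. The lists cover the targeted genes, PU.1 targets, stem cell, myeloid, erythroid, megakaryocyte, lymphoid and stromal markers, MHC class II, cell cycle, metabolism, stress and signalling genes, DNA methylation enzymes and transcription factors. Several genes stand in more than 1 list, and many markers of mature cells are also transcribed in progenitors.

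Genes named for a comparison followed a rule: Spi1 and Tet2 always, then the 10 largest rises and 10 largest falls that passed 0.05 with a mean of at least 1 log2 CPM and no overlap between the 2 groups (overlap was allowed for AML against Normal and for interactions), and up to 4 passing members of each list by smallest p. Predicted, clone-named and immunoglobulin or T cell receptor genes, pseudogenes, Xist and Y-linked genes were left out of that rule. The result of 1 gene that the rule named is not reported here. Where every library of a group had 0 counts the fold is a lower bound, computed from 3 counts over the group and written as at least.

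Alternatives were DESeq2 size factors, no filter on low counts (at least 1 count), DESeq2 1.42.0, limma voom with quality weights, non-robust edgeR, a fit of the compared groups alone, leaving out each library, a term for sex read from Xist (at least 100 CPM) and Y-linked genes (at least 10 CPM), which leaves out the 2 libraries where neither was seen, and a term for the number in the library titles (1 to 7 against 8 to 17). Each range of numbers holds every genotype; the labels do not call it a batch. Range 1 to 7 has 2 WT libraries and 1 of each other genotype, so its spread rests on WT alone; in range 8 to 17 WT and URE het Tet2 het have 1 library each. After the data were seen, fits within each range, fits of the 12 Normal libraries with the range term, and fits without the 2 libraries that had neither Xist nor Y-linked transcripts were added. Other splits of the libraries were refitted in the same way, and for AML against Normal also within the ranges with the range term. For the mixture of Normal cells, a limit on the SD of the log2 ratios (1.5 times the highest Normal library) was tried with the ratios already seen; it would have excluded 1 share in both libraries and was not kept, since its limit was chosen late and the genes were picked by their levels in the Normal libraries. The level of chromosome 2 was then weighed, also with its values already seen, against the level that the upper 95% limit of the share (sign test of the median) implies. The procedure was tested on simulated counts with 200 changed genes, 50 at each fold. For AML against Normal edgeR called 4, 20, 44 and 49 of 50 genes changed 1.5, 2, 4 and 8-fold with 5 false calls; for URE het Tet2 KO against Tet2 KO it called 0, 5, 27 and 43 with 2 false calls. DESeq2 made 43 to 44 false calls there. Principal components used the 2000 most variable genes. Positions along chromosomes were compared through the median log2 ratio to the Normal libraries of genes with at least 3 log2 CPM. Files were read with the R package data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9.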

Results

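Transcript levels were measured in cKit+ bone marrow progenitors of mice that carried a heterozygous deletion of the upstream regulatory element (URE) of Spi1, an enhancer of the gene for the myeloid and lymphoid transcription factor PU.1, with loss of 1 copy (het) or of both copies (KO) of Tet2, a DNA demethylase often mutated in clonal haematopoiesis. There were 3 wild-type (WT), 3 URE het, 3 Tet2 het and 3 Tet2 KO libraries, all labelled Normal, and 2 URE het Tet2 het and 3 URE het Tet2 KO libraries, all labelled acute myeloid leukaemia (AML). Gene counts ran from 21.1 M (Tet2 het replicate 1) to 38.3 M (URE het Tet2 KO replicate 2) per library. The title of the study sets clonal haematopoiesis against malignant transformation, so the question here was what the single mutants changed and what the compound mutants changed beyond them. Every AML library was a compound mutant, so disease and compound genotype cannot be told apart.

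Spi1 RNA was lowest in the compound mutants. Spi1 (ENSMUSG00000002111.8, chromosome 2, 91082390 to 91115756, GRCm38) stood at 94.6 ± 34.5 CPM in WT (SD, n = 3), 63.4 ± 24.2 in URE het (n = 3), 79.5 ± 38.5 in Tet2 het (n = 3), 84.0 ± 46.0 in Tet2 KO (n = 3), 28.2 ± 9.38 in URE het Tet2 het (n = 2) and 39.6 ± 51.2 in URE het Tet2 KO (n = 3). In 4 of the 5 AML libraries it lay between 7.83 and 34.9 CPM, below all 12 Normal libraries (45.3 to 137 CPM). URE het Tet2 KO replicate 1 was the exception at 98.6 CPM. Between AML and Normal the log2 fold change was -1.25 ± 0.52, which did not pass in edgeR (adjusted p = 0.135). Without URE het Tet2 KO replicate 1 it was -2.24 (adjusted p = 0.00094), within the libraries numbered 8 to 17 it was -1.56 (adjusted p = 0.00137), and with a term for that range it was -1.30 (adjusted p = 0.0303). Within those numbered 1 to 7 it was -1.33; there every mutant genotype has 1 library and the spread rests on 2 WT libraries. Spi1 passed with DESeq2 (adjusted p = 0.0416) and voom (adjusted p = 0.0171) as well; over all alternatives its adjusted p ran from 0.000604, within 1 to 7, to 0.451, in a fit with a sex term that leaves out 2 of the 5 AML libraries. In URE het against WT it was -0.58 ± 0.72 (adjusted p = 1), and -0.13 with the range term (adjusted p = 0.982). Spi1 itself was lower by 1.29 in the later range in the fit of all 17 libraries (adjusted p = 0.0121), of which URE het holds 2 libraries and WT 1.

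Among the Normal libraries Tet2 RNA was lowest in Tet2 KO, and the compound mutants did not show that fall. Tet2 (ENSMUSG00000040943.12, chromosome 3, 133463679 to 133545139) stood at 119 ± 12.5 CPM in WT (SD, n = 3), 145 ± 27.1 in URE het (n = 3), 105 ± 11.1 in Tet2 het (n = 3) and 82.5 ± 3.30 in Tet2 KO (n = 3), where the 3 libraries ran from 80.2 to 86.3 CPM and lay below every other Normal library. It was 195 ± 55.1 CPM in URE het Tet2 het (n = 2) and 133 ± 36.8 in URE het Tet2 KO (n = 3). The Tet2 KO difference from WT was -0.53 ± 0.22 on the log2 scale (edgeR adjusted p = 1). In AML against Normal Tet2 was 1.46-fold higher (log2 fold change 0.55 ± 0.14, adjusted p = 0.0261). That call ended without URE het Tet2 het replicate 1 (adjusted p = 0.18), URE het replicate 2 (0.0577), Tet2 het replicate 3 (0.05), Tet2 KO replicate 2 (0.0538) or URE het Tet2 KO replicate 3 (0.104), and within libraries 8 to 17 (0.40, adjusted p = 0.112); over all alternatives adjusted p ran from 0.0075 to 0.309. The counts cover whole genes, exons outside any deletion included, and the URE is not part of the Spi1 transcript, so these levels do not check either allele.

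**Figure D1:**
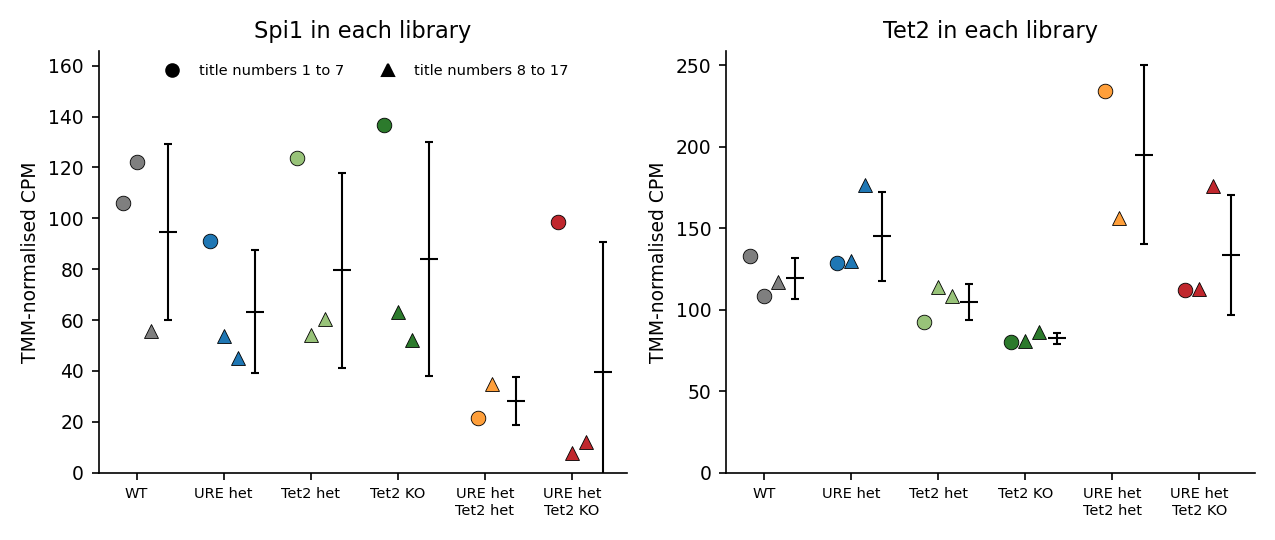
CPM of Spi1 and Tet2 in each library by genotype group; circles are libraries numbered 1 to 7, triangles those numbered 8 to 17, and bars are mean ± SD. Spi1 lies between 7.83 and 34.9 CPM in 4 of the 5 AML libraries, and Tet2 between 80.2 and 86.3 CPM in Tet2 KO.

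AML against Normal asked what separates the compound mutants from every other genotype, and here the changes were large. Folds come from group means on the log2 scale and differ from the ratio of the mean CPM beside them. Svep1, an adhesion protein of the extracellular matrix, rose 397-fold (log2 fold change 8.63 ± 0.89, adjusted p = 0.000388), from 0.308 ± 0.203 CPM in 12 Normal libraries to 127 ± 149 in 5 AML libraries (SD). Thbs4, another matrix glycoprotein, rose by 8.33 ± 1.04 on the log2 scale (adjusted p = 0.000733). Csf2rb, the receptor chain shared by GM-CSF, IL-3 and IL-5, rose 1.72-fold (131 ± 12.4 CPM, n = 12, to 251 ± 100 CPM, n = 5). MHC class II genes were lower as a list at the preset correlation (adjusted p = 3.26e-10) and not at an estimated one (0.111), and URE het Tet2 het replicate 2 stayed within the Normal range (mean 2.31 log2 CPM, Normal libraries 1.90 to 4.06). H2-Aa was 24.1-fold lower (29.3 ± 24.2 CPM, n = 12, to 2.30 ± 4.74 CPM, n = 5) and Cd74, the invariant chain that escorts class II molecules, 16.9-fold lower. In edgeR 2188 of 19951 genes passed, 1385 higher and 803 lower in AML, where 998 genes would reach an unadjusted p under 0.05 by chance and 5252 did. The balance of directions was not stable: DESeq2 gave 1627 higher and 1628 lower, voom 788 and 759, and edgeR 1872 and 1935 without URE het Tet2 het replicate 2 and 2091 and 1907 without URE het Tet2 KO replicate 1.

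Some myeloid genes rose, though the list of primary granule and GMP genes did not pass. Gfi1, a repressor that directs granulocyte formation, rose 2.48-fold (log2 fold change 1.31 ± 0.20, adjusted p = 0.00144) and was above all Normal libraries in 4 of 5 AML libraries. Cebpa, the granulocyte lineage factor, rose 3.25-fold to 65.2 ± 43.1 CPM (n = 5), Ctsg, a neutrophil granule protease, rose by 0.99 ± 0.27 (adjusted p = 0.0311), and Cdkn1c, a cell cycle inhibitor of quiescent stem cells, rose 4.35-fold. F13a1, the coagulation factor XIII subunit made by monocytes, rose 4.97-fold and fibronectin (Fn1) 17.3-fold. Igll1, a surrogate light chain of pre-B cells, rose 208-fold against the direction of most B cell genes. Cebpa, F13a1, Fn1 and Igll1 no longer passed without URE het Tet2 het replicate 1 (adjusted p = 0.306, 0.0827, 0.206 and 0.0747). The Ctsg call was lost without that library (0.105), WT replicate 2 (0.0529), URE het replicate 2 (0.0534), Tet2 het replicate 3 (0.0584) and URE het Tet2 KO replicates 2 (0.0839) and 3 (0.0609).

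The falls covered several other lineages. Epx, the eosinophil peroxidase, fell 23.5-fold, Prss34, a basophil protease, 22.1-fold, and Rnase6, an antimicrobial ribonuclease, 20.8-fold (log2 fold change -4.38 ± 0.54, adjusted p = 0.000733), below every Normal library in 5 of 5 AML libraries for Prss34 and Rnase6. Among B lymphoid genes Rag1, a recombinase of antigen receptor genes, fell by 5.96 and Ebf1, a B lineage factor, by 5.12 on the log2 scale, while Il7r, the interleukin 7 receptor, was 6.42-fold lower. Gfi1b, a factor of erythroid and megakaryocyte precursors, was 11.7-fold lower. Irf4, a lymphoid and dendritic factor, was 5.92-fold and Tet1, a second DNA demethylase, 3.15-fold lower (51.1 ± 14.5 CPM, n = 12, to 15.5 ± 11.4 CPM, n = 5). Mef2c, a PU.1 target in lymphoid progenitors, fell 2.31-fold and S100a8, an antimicrobial subunit of late neutrophils, 2.68-fold. Angpt1, a ligand that keeps stem cells quiescent, fell by 2.95 ± 0.73. Meis1, the stem cell and leukaemia homeobox gene, was 7.54-fold lower (adjusted p = 0.0485); that call held in edgeR only without URE het Tet2 KO replicate 1 or URE het Tet2 het replicate 2 among the 17 omissions, whose adjusted p ran from 0.00129 to 0.091.

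**Figure D2:**
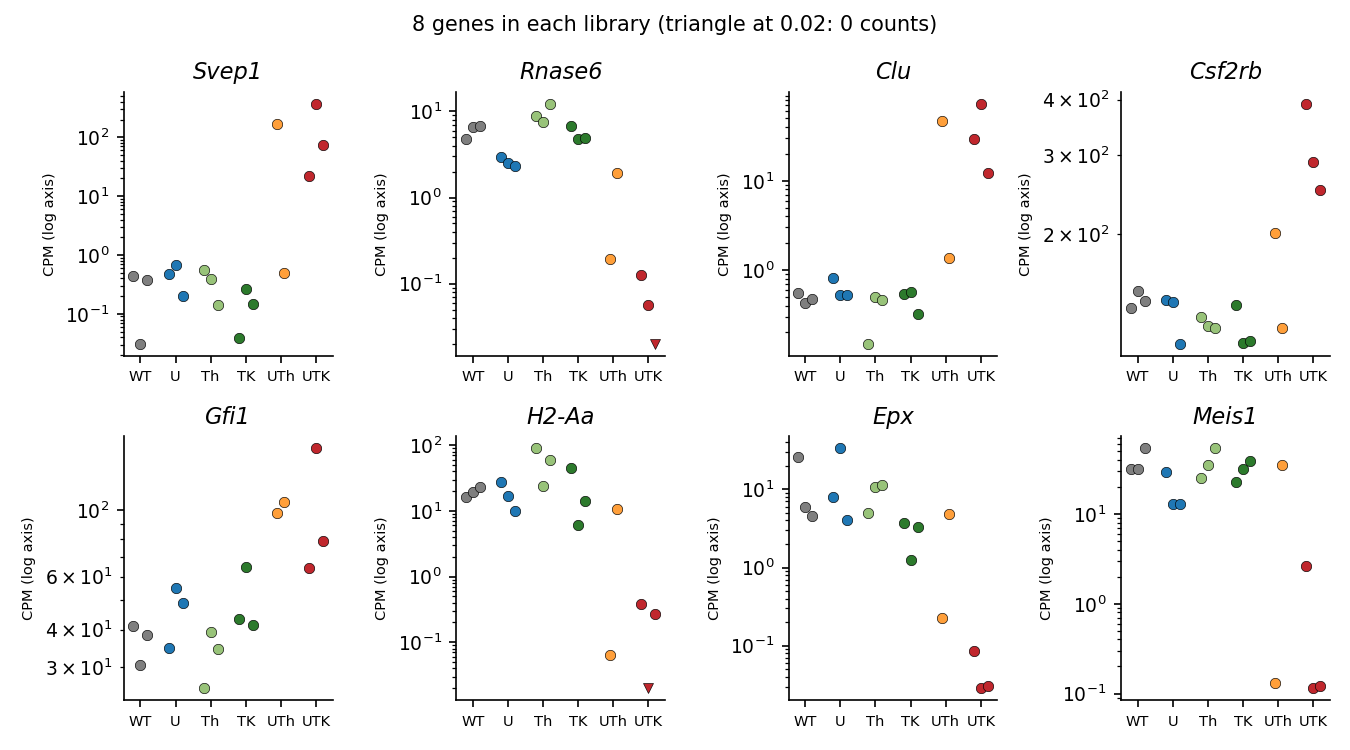
CPM on a log axis of named genes in each library; groups are WT, URE het (U), Tet2 het (Th), Tet2 KO (TK), URE het Tet2 het (UTh) and URE het Tet2 KO (UTK), and triangles at 0.02 stand for 0 counts. URE het Tet2 het replicate 2 has 0.488 CPM of Svep1 and 10.8 CPM of H2-Aa, within the ranges of the Normal libraries.

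The 5 AML libraries were not alike. On the first principal component, with 56.1% of the variance, URE het Tet2 het replicate 1 (116.7) and URE het Tet2 KO replicates 2 (123.7) and 3 (110.1) stood far from the Normal libraries (-43 to -9), whereas URE het Tet2 KO replicate 1 (19.3) and URE het Tet2 het replicate 2 (-14) lay closer. MHC class II genes followed another order: H2-Aa was at 0.381 CPM in URE het Tet2 KO replicate 1 and 10.8 CPM in URE het Tet2 het replicate 2. The number of called genes was 845 without URE het Tet2 het replicate 1, 1229 and 1291 without URE het Tet2 KO replicates 2 and 3, 3998 without URE het Tet2 KO replicate 1 and 3807 without URE het Tet2 het replicate 2. Without the 2 libraries that had neither Xist nor Y-linked transcripts, an alternative chosen after the data were seen, it was 610, and 45 when a sex term was added to that fit, in which the 3 remaining AML libraries all read as female.

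**Figure D3:**
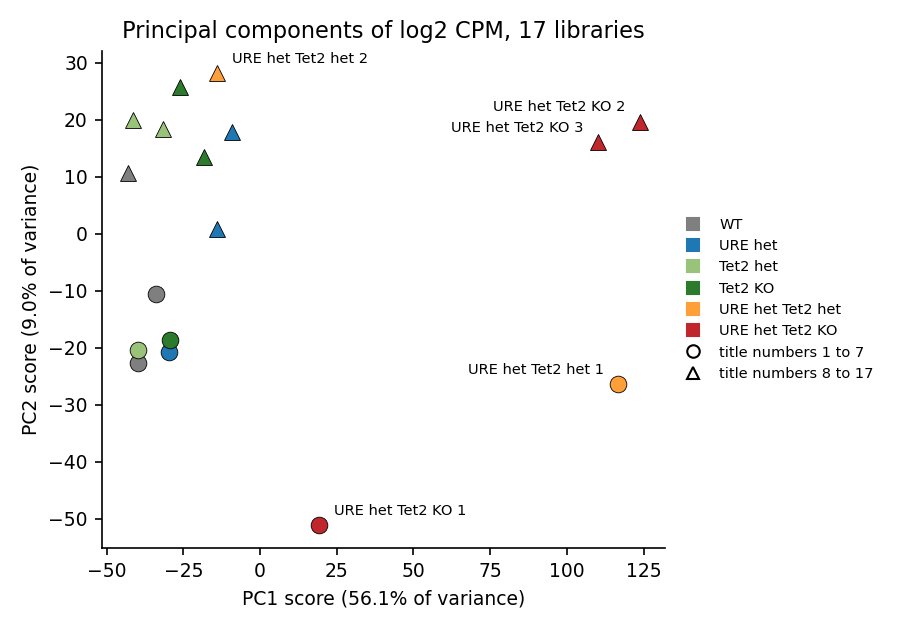
First and second principal components of the 17 libraries, computed from the 2000 most variable genes and coloured by genotype group. URE het Tet2 KO replicate 1 lies at 19.3 and URE het Tet2 het replicate 2 at -14 on the first component, against 110.1 to 123.7 for the other AML libraries.

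Title numbers set the libraries apart as well. In the 12 Normal libraries 6601 genes differed between numbers 1 to 7 and 8 to 17, 3117 higher and 3484 lower in the later range. In the 5 AML libraries alone, with fewer libraries to estimate the spread, 0 genes passed. Egr1, an immediate early transcription factor, was lower by 2.86 on the log2 scale in the later range of the 12 Normal libraries (edgeR adjusted p = 0.0188). Thbs1 was lower by 2.93 in the same fit (adjusted p = 0.0197). AML against Normal called 4307 genes within 8 to 17, where URE het Tet2 het has 1 library, and 3664 with the range as a term. Calls within 1 to 7 are left out here, since each mutant genotype has 1 library there. In the later range Csf2rb was higher by 0.53, Gfi1 by 1.34 and Svep1 by 5.09, and H2-Aa was at -3.98, Cd74 at -3.37, Rnase6 at -4.39 and Epx at -4.10 (adjusted p = 0.0444), all passing. In the earlier range the same 7 genes stood at 1.01, 1.19, 8.05, -7.85, -6.31, -5.12 and -5.61.

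Of 24 gene lists, 13 were lower in AML by camera and none higher. MHC class II was lower in 10 of 10 members (median log2 fold change -2.77, adjusted p = 3.26e-10), with 0 members higher and 9 lower among all genes and 9 lower adjusted over the list alone. The lists for mast cells, basophils and eosinophils (-2.71, 2 higher and 10 lower), B cells (-2.24, 1 higher and 10 lower), erythroid cells (-1.70, 0 and 3), stem cells (-1.61, 2 and 11), the Hoxa-Meis1 programme (-1.41, 1 and 3), megakaryocytes (-1.12, 0 and 5), late neutrophils (-1.06, 0 and 6), T and NK cells (-0.62, 1 and 2), S phase and G2/M (-0.44, 0 and 3), transcription factors (-0.46, 2 and 6), monocytes and dendritic cells (-0.33, 2 and 5) and PU.1 targets (-0.20, 1 and 3) passed too. Adjusted over the list alone, higher and lower counts were 2 and 13 for mast cells, 2 and 13 for B cells, 0 and 13 for erythroid cells, 5 and 15 for stem cells, 2 and 5 for Hoxa-Meis1, 0 and 5 for megakaryocytes, 1 and 6 for late neutrophils, 1 and 4 for T and NK cells, 0 and 4 for S phase and G2/M, 3 and 10 for transcription factors, 3 and 7 for monocytes and 1 and 3 for PU.1 targets. None of the 13 held when the correlation was estimated: adjusted p = 0.0536 with an estimated correlation for B cells, 0.0939 for megakaryocytes, 0.111 for MHC class II and mast cells, and 0.132 to 0.644 for the rest. With fry 12 lists passed.

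The other 11 lists did not pass. Primary granule and GMP genes had a median of 0.26 with 4 of 18 members higher, Ctsg, Gfi1, Cebpa and Rgcc. Medians were 0.35 for p53 targets (3 higher, 0 lower), 0.05 for lysosome genes (2 and 1), 0.01 for interferon-stimulated genes (0 and 0), -0.04 for Myc and ribosome biogenesis (0 and 0), -0.10 for oxidative phosphorylation (0 and 1), -0.16 for DNA methylation enzymes (2 and 1), -0.30 for immediate early genes (0 and 0), -0.32 for stromal and endothelial markers (1 and 1), -0.35 for the targeted loci (1 and 0) and -0.52 for NF-kB and inflammatory genes (2 and 2).

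**Figure D4:**
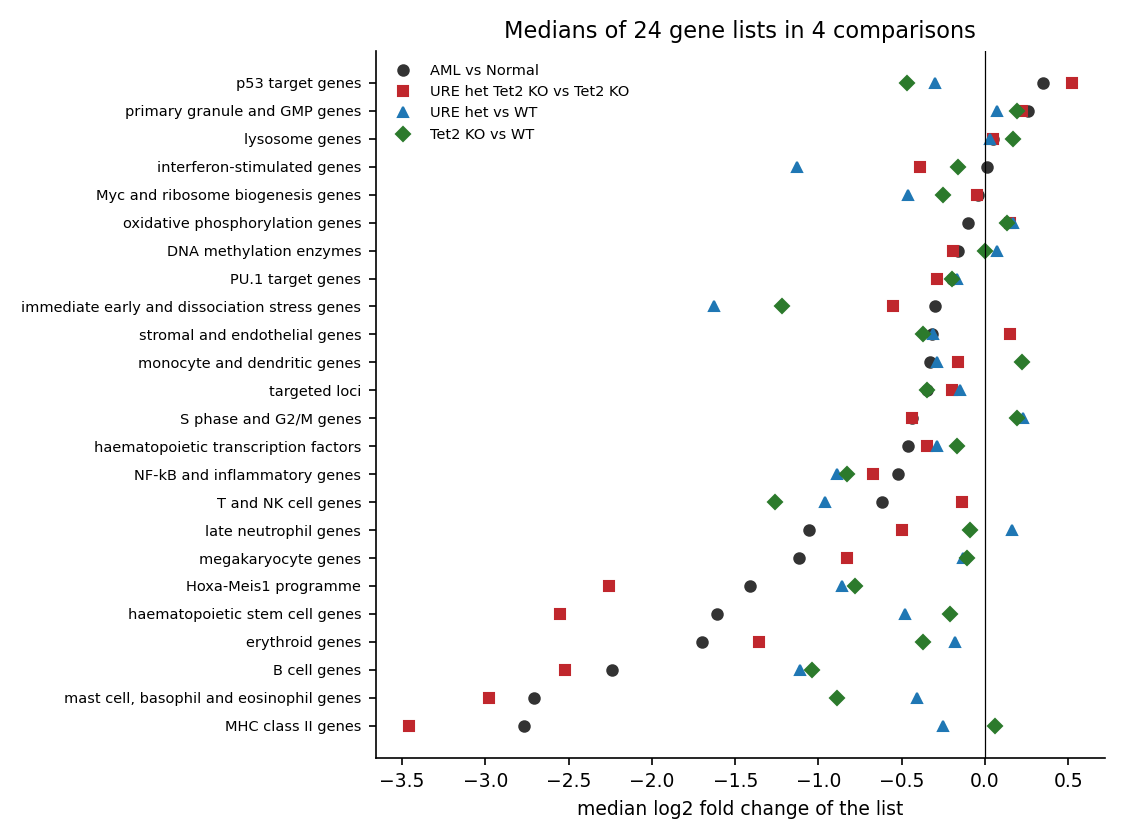
Median log2 fold change of the 24 gene lists in 4 comparisons. MHC class II genes have a median of -2.77 in AML against Normal and -3.46 in URE het Tet2 KO against Tet2 KO, and immediate early genes -1.63 in URE het and -1.22 in Tet2 KO against WT.

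A stretch of chromosome 2 that holds Spi1 was lower as a whole in 3 AML libraries. The interval was chosen from these 3 libraries. Its 364 genes, from 60 to 160 Mb, stood at a median of 51.6% of the Normal level in URE het Tet2 het replicate 1, 52.6% in URE het Tet2 KO replicate 2 and 52.1% in URE het Tet2 KO replicate 3. The same genes were at 99.8% in URE het Tet2 KO replicate 1, 97.8% in URE het Tet2 het replicate 2 and 96.9 to 103% in the 12 Normal libraries. These 3 libraries had 21.6, 7.83 and 12.2 CPM of Spi1. Of the 803 genes lower in AML, 93 (11.6%) lay on chromosome 2, which held 7.69% of the genes tested. DNA was not measured.

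**Figure D5:**
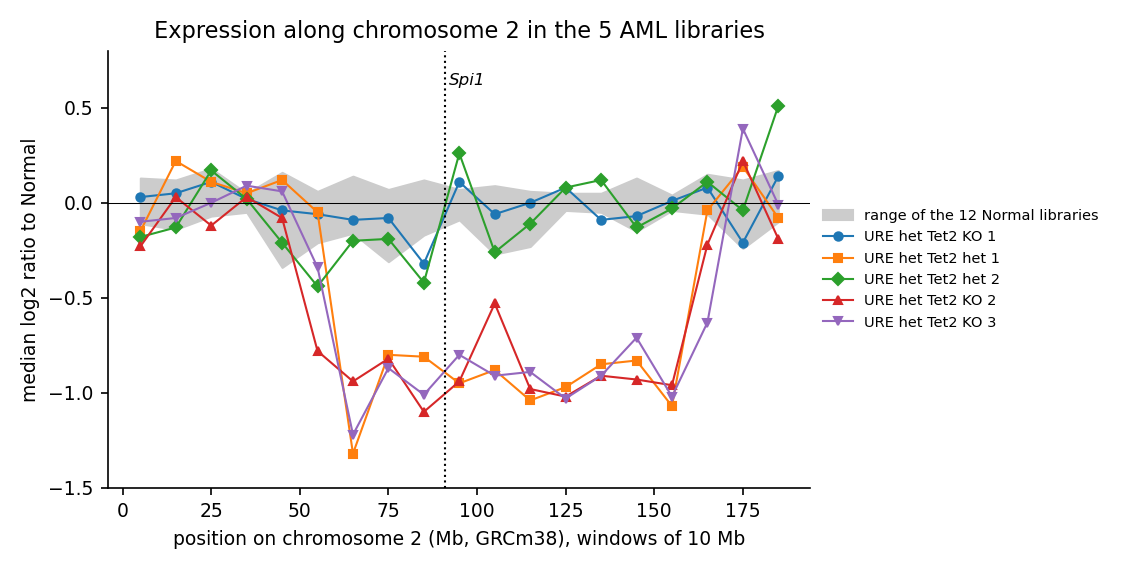
Median log2 ratio to the Normal libraries of genes in 10 Mb windows along chromosome 2 for each AML library; grey marks the range of the 12 Normal libraries and the dotted line the position of Spi1. Over the 364 genes from 60 to 160 Mb, medians are -0.95, -0.93 and -0.94 in 3 libraries and 0 and -0.03 in the other 2.

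URE het Tet2 KO against Tet2 KO asked what the enhancer deletion adds to loss of Tet2. Clu, a secreted chaperone, rose 79.7-fold (log2 fold change 6.32 ± 1.03, adjusted p = 0.0281), from 0.475 ± 0.132 CPM in Tet2 KO (SD, n = 3) to 37.9 ± 31.1 in the compound (n = 3). Csf2rb rose 2.54-fold (122 ± 13.8 to 311 ± 72.2 CPM, n = 3 each) and its relative Csf2rb2 2.80-fold. Svep1 rose by 9.94 ± 1.81, and Thy1, a surface glycoprotein of T cells and early progenitors, rose 35.9-fold. Cd22, an inhibitory B cell receptor, fell 35.8-fold (log2 fold change -5.16 ± 0.58, adjusted p = 0.00285), Cd74 47.0-fold, H2-Aa 104-fold, Rnase6 90.9-fold (-6.51 ± 0.82, adjusted p = 0.00609) and Dntt, the template-free polymerase of lymphoid progenitors, 90.5-fold.

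Several lymphoid and dendritic genes had 0 counts in all 3 URE het Tet2 KO libraries. The dendritic lectin Cd209a was at least 58.3-fold lower than in Tet2 KO, the cation channel gene Trpc6, a member of the stem cell list, at least 58.2-fold, Rag1 at least 29.9-fold and Ebf1 at least 17.1-fold. Kcng1, a potassium channel subunit, was at 0.0101 ± 0.0175 CPM against 5.98 ± 3.27 (n = 3 each), and Gfi1b at 0.0282 ± 0.0488 against 1.39 ± 0.211. Irf4 was 7.73-fold lower. In total 195 genes passed in edgeR, 79 higher and 116 lower, and 3015 had an unadjusted p under 0.05. MHC class II had a median of -3.46 with 4 members lower and 9 lower adjusted over the list alone (camera adjusted p = 4.97e-10, and 0.154 with an estimated correlation). B cell genes had 5 lower, stem cell genes 1 and mast cell genes 0 among all genes, and 11, 15 and 11 lower adjusted over the list alone (adjusted p = 0.0916, 0.209 and 0.161 with an estimated correlation). Over the 24 lists, 15 passed with the preset correlation, 0 with the estimated one and 9 with fry.

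Single libraries decided these calls. The count fell to 4, 5 and 4 without Tet2 KO replicates 1, 2 and 3, to 3 and 8 without URE het Tet2 KO replicates 2 and 3, and was 1799 without URE het Tet2 KO replicate 1. Cd22 passed in each of those omissions; Rnase6 had an adjusted p of 0.0666 without URE het Tet2 KO replicate 2, and Cd74 and Csf2rb passed only without URE het Tet2 KO replicate 1 (otherwise adjusted p = 0.0578 to 0.112 and 0.0538 to 0.0953). So did the other genes named, except Clu, which also passed without URE het Tet2 KO replicate 3 (0.0381), and Cd209a, which also passed without Tet2 KO replicate 2 or 3. Within title numbers 8 to 17 Cd74 was at -4.55 and passed, as did Csf2rb, and 3512 genes passed, with 415 for the range term. Spi1 was at -1.09 ± 0.73 (adjusted p = 0.532) over all libraries, -0.48 within 1 to 7, with 1 library a group, and -2.53 (adjusted p = 0.000285) within 8 to 17, where the alternatives ran up to an adjusted p of 0.852, and Tet2 at 0.69 ± 0.23 (adjusted p = 0.139).

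URE het Tet2 het against Tet2 het asked the same for 1 lost copy of Tet2, and no gene passed in edgeR, where 2652 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0989. MHC class II genes were lower in 10 of 10 members (median log2 fold change -2.32, camera adjusted p = 3.22e-10, 0.189 with an estimated correlation), 8 of them lower adjusted over the list alone. In URE het Tet2 het the list mean was -1.01 log2 CPM in replicate 1 and 2.31 in replicate 2. In Tet2 het it ran from 2.94 to 4.06, so replicate 1 carried most of the fall. B cell genes had a median of -1.85 (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.112 with an estimated correlation) and mast cell, basophil and eosinophil genes -1.58 (1 and 4, 0.189). Spi1 was at -1.49 ± 0.85 (adjusted p = 0.473) and Tet2 at 0.90 ± 0.25 (adjusted p = 0.161). DESeq2 called 599 genes and voom 0. Without URE het Tet2 het replicate 2 edgeR called 1219 genes, without replicate 1 it called 123, and it called 838 within title numbers 8 to 17, where URE het Tet2 het has 1 library, and 145 with the range term.

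The 2 compound genotypes moved many genes the same way. Across 19951 genes the log2 changes over Tet2 het and over Tet2 KO correlated at Pearson 0.601 and Spearman 0.46; genes are not independent replicates, and the 2 comparisons share no library. Of the 195 genes called in URE het Tet2 KO, 191 (97.9%) changed in the same direction in URE het Tet2 het, against 66% of all genes. No gene passed in both, since none passed in URE het Tet2 het; DESeq2 called 242 in both. Pearson's r was 0.281 and 0.183 within title numbers 1 to 7 and 8 to 17, 0.624 with the range term, and 0.188 without URE het Tet2 het replicate 1. Compared directly, URE het Tet2 KO had 56.8-fold less Cd22 than URE het Tet2 het (log2 fold change -5.83 ± 0.60, adjusted p = 0.00151) and 46.7-fold less Xlr4a, an X-linked lymphocyte-regulated gene (-5.55 ± 0.73, adjusted p = 0.0155). Those were the only calls by edgeR, with 2344 genes at an unadjusted p under 0.05; without URE het Tet2 KO replicate 2 or 3 Xlr4a did not pass (0.105 and 0.0875), and without URE het Tet2 het replicates 1 and 2 or URE het Tet2 KO replicate 1 the count was 1015, 63 and 26. With the range term 14 genes passed.

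Against WT, URE het Tet2 KO showed the whole distance of the compound from unmutated marrow. Epx and Dntt each fell 252-fold, Cd74 51.0-fold and Il7r 15.7-fold, and Irf4 fell by 3.91 on the log2 scale, while Ctsg rose 3.34-fold, Gfi1 2.76-fold and Csf2rb 2.19-fold. Lmo2, a stem cell and erythroid cofactor, fell 2.06-fold. Ebf1 and Rag1 had 0 counts in the compound and were at least 68.4-fold and at least 66.1-fold lower. In edgeR 676 genes passed, 263 higher and 413 lower. B cell genes were the 1 list that kept its call with an estimated correlation (median -3.23, adjusted p = 0.0143), with 11 lower and 1 higher among all genes and 14 lower adjusted over the list alone. The count was 100, 16 and 128 without WT replicates 1, 2 and 3, 19 and 40 without URE het Tet2 KO replicates 2 and 3, and 2521 without its replicate 1. Of the genes just named, only Ebf1 kept its call without WT replicate 2, and it had an adjusted p of 0.0501 without URE het Tet2 KO replicate 2. Within title numbers 8 to 17, with 1 WT library, 2789 genes passed, and 1133 with the range term. URE het Tet2 het against WT called 0 genes in edgeR (2746 at an unadjusted p under 0.05, DESeq2 695, voom 0), with 1172 and 170 without its replicates 2 and 1 and 176 with the range term.

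Against URE het, which asks what loss of Tet2 adds to the enhancer deletion, URE het Tet2 KO had 11.4-fold more Cdkn1c (log2 fold change 3.52 ± 0.62, adjusted p = 0.0346), 61.1-fold more Clu and 2.35-fold more Csf2rb. Rnase6 was 43.0-fold, Cd74 36.7-fold, Cd22 19.4-fold and Epx 314-fold lower. By Xist and Y-linked genes every URE het library read as male. No URE het Tet2 KO library did: replicates 1 and 3 read as female, and replicate 2 had neither transcript. The main fit holds no term for sex, so these calls cannot be assigned to loss of Tet2 alone. In edgeR 71 genes passed, 28 higher and 43 lower, with 3752 within title numbers 8 to 17 and 258 with the range term. The count was 0, 9 and 2 without URE het replicates 1, 2 and 3, 0 without URE het Tet2 KO replicate 2 or 3, and 1789 without its replicate 1. URE het Tet2 het against URE het called 0 genes in edgeR (2634 at an unadjusted p under 0.05, DESeq2 530, voom 0), with 855 and 165 without its replicates 2 and 1 and 108 with the range term.

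Each single genotype against WT asked whether the mutations that precede transformation change the progenitors alone, and no gene passed in edgeR. In the simulated counts for Tet2 KO against WT, edgeR called 2 of 50 genes changed 2-fold and 33 of 50 changed 4-fold. Changes of 2-fold would therefore mostly be missed. URE het against WT had 753 genes at an unadjusted p under 0.05, Tet2 het 585 and Tet2 KO 512, where chance gives 998. That fit ignores the title range, which the groups hold in unequal parts, and shares its spread with the AML libraries. With the range term and all 17 libraries URE het had 1302 such genes. In the 12 Normal libraries alone with a range term the numbers were 2733, 2087 and 1584, and 16, 0 and 0 genes passed. This last fit changes both the term and the libraries, so the rise cannot be assigned to the range alone. DESeq2 called 7, 1 and 12 genes and voom 79, 0 and 86. In URE het, B cell genes were lower (median log2 fold change -1.11, 2 of 20 members higher, camera adjusted p = 1.46e-10), with 0 called among all genes and 5 lower adjusted over the list alone; this call held with an estimated correlation (adjusted p = 0.0324). T and NK cell genes were lower too (median -0.96, 3 of 20 members higher, 0 called among all genes or over the list alone, camera adjusted p = 0.00143), a call that ended with an estimated correlation (0.477). PU.1 targets had a median of -0.17 (adjusted p = 0.00167, 0.547 with an estimated correlation) and Myc and ribosome biogenesis genes -0.46, with 7 lower adjusted over the list alone (adjusted p = 0.221 with an estimated correlation). In the 12 Normal libraries PU.1 targets also had a median of -0.65 in the later title range relative to the earlier. That range holds 2 of the 3 URE het libraries and 1 of the 3 WT libraries. The fall of PU.1 targets in URE het therefore cannot be told apart from the range difference. In Tet2 KO, B cell genes were lower in 20 of 20 members (median -1.04, 1 lower adjusted over the list alone, adjusted p = 0.0706 with an estimated correlation). MHC class II genes had a median of 0.82 in Tet2 het (adjusted p = 0.735 with an estimated correlation). Immediate early genes were lower in 25 of 25 members in all 3 genotypes (medians -1.63, -1.15 and -1.22; 0.221, 0.488 and 0.368 with an estimated correlation), and they differed between the title ranges too (median -1.62 in the later range). WT had 2 of 3 libraries in the range 1 to 7, the single genotypes 1 of 3. By Xist and Y-linked genes every URE het library read as male, WT replicates 1 and 2 as female and WT replicate 3 as male. Preset camera called 15, 8 and 12 lists in the 3 genotypes and fry 1, 0 and 0. Within title numbers 8 to 17, with 1 WT library, edgeR called 10, 0 and 0 genes, and with the range term and all 17 libraries 0, 0 and 0.

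Whether the enhancer deletion acted differently with Tet2 lost was tested as an interaction. No gene passed for Tet2 het (edgeR, 1836 at an unadjusted p under 0.05, DESeq2 103, voom 0) or for Tet2 KO (1618, DESeq2 151, voom 1782), so whether any 1 gene differed depended on the method. Spi1 had an interaction of -0.91 ± 1.09 with Tet2 het (adjusted p = 0.823) and -0.51 ± 1.02 with Tet2 KO (adjusted p = 0.953), and Tet2 of 0.62 ± 0.33 (adjusted p = 0.595) and 0.41 ± 0.32 (adjusted p = 0.8). MHC class II genes were lower in 10 of 10 members in the interaction with Tet2 KO (median -3.35, 0 called among all genes, 7 lower adjusted over the list alone, adjusted p = 0.218 with an estimated correlation). Without URE het Tet2 KO replicate 1 the count was 279, and without URE het Tet2 het replicate 2 it was 284 for Tet2 het. Within title numbers 8 to 17, where WT and URE het Tet2 het have 1 library each, 48 genes passed for Tet2 het and 723 for Tet2 KO, and 0 and 0 with the range term.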

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

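Tests of a mixture with Normal cells, by MHC class II genes, by genes near 0 in the other AML libraries and by chromosome 2, of too few counts for Xist and Y-linked genes, of loss of the Y chromosome or the inactive X, and of other splits with the title range as a term were chosen after the result was seen; the other tests of this part were chosen before.

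In the 5 AML libraries 2 gene lists had 1 library far from the others. URE het Tet2 het replicate 2 had a mean of 2.27 log2 CPM over haematopoietic stem cell genes against -0.45 to 0.30 in the other 4 (gap over range 0.724), and 2.31 over MHC class II genes against -1.01 to -0.31 (0.789). The limit for 5 libraries is 0.71, 29 measures were tested, and chance alone passes it in about 1 of 20.

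The first pattern weighed is that URE het Tet2 het replicate 2 and URE het Tet2 KO replicate 1 lay close to the Normal libraries on the first principal component; the design holds no group for stage or leukaemic burden, so no biological explanation was tested. A mislabelled Normal library is argued against for both: alone against the 12 Normal libraries they differed at 1005 and 510 genes, where each Normal library differed from the other 11 at 0 or 1; a lower depth is argued against for the pair, with 37.7 M gene counts in URE het Tet2 het replicate 2 and 23.5 M in URE het Tet2 KO replicate 1, though the latter was the lowest of the 5 AML libraries and Normal libraries began at 21.1 M. A set of 41 genes was near 0 in the other 3 AML libraries. In URE het Tet2 KO replicate 1 their median was 0.251 of the Normal mean (upper 95% limit 0.734). The limit counts these genes as independent, which they are not, so it is a rough bound. It would place the low interval of chromosome 2 at no more than 87.4% of the Normal level. The interval stood at 99.8% (Normal libraries from 96.9%). By that rough bound, Normal progenitors mixed into cells like the other 3 AML libraries are argued against for URE het Tet2 KO replicate 1. For URE het Tet2 het replicate 2 this stays open, with a median of 0.823 (limit 1.03) and the interval at 97.8%; in each library 9.76% of the 41 genes lay below 0.2 of the median, which looks at low ratios alone, and the SD of the log2 ratios was 1.24 here and 2.09 in the former against 0.367 to 0.727 in Normal libraries. A mixture with leukaemic cells that lack the chromosome 2 change stays open in both: the median MHC class II gene stood at 1.58 times the lowest Normal library in URE het Tet2 het replicate 2 and at 0.241 in URE het Tet2 KO replicate 1, inside the 0.17 to 0.295 of the other 3, and H2-Aa at 0.381 CPM there, against 6.19 to 89.8 in Normal libraries, goes against a share near 0.251 that brings all Normal transcripts.

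The second pattern is the difference between title numbers 1 to 7 and 8 to 17, at 6601 genes in the 12 Normal libraries; mitochondrial rRNA took 24.6 to 28.8% of gene counts in the 7 libraries of the first range and 29.4 to 41.1% in the 10 of the second. Unequal sex of the ranges is argued against, since 6297 autosomal genes passed without a sex term and 5489 with it. A difference in preparation or sequencing cannot be told apart from other differences between the ranges: the range difference correlated at 0.395 across genes between Normal and AML libraries, below the 0.5 set for that explanation and above the 0.2 set against it, and genes are not independent. A bias by GC content or gene length stays open as well, with Spearman correlations of -0.282 and -0.155 across genes. Age, date and cohort are not given per library, and no biological explanation was tested.

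The third pattern is that URE het Tet2 het replicate 1 and URE het Tet2 KO replicate 2 had neither Xist nor Y-linked transcripts. They had 101 and 80 counts of Xist and 6 and 24 of the Y-linked genes, where at least 3427 were to be seen at the lowest male or female level, so too few counts is argued against. Loss of the whole X chromosome from expression is argued against by X-linked genes, whose median log2 ratio to the Normal libraries was 0.1 in the higher of the 2 and above -0.2 in both. Loss of the Y chromosome or of the inactive X could account for it and stays open, with 3 genes that escape X inactivation at 1.34 and 1.13 times the male Normal median (mean 1.24): the first lies outside the male Normal range of 0.892 to 1.31, which overlaps the female one of 1.1 to 1.56. The 3 genes leave out Kdm6a, which also escapes X inactivation. Kdm6a stood at 0.683 CPM in URE het Tet2 het replicate 1 and 45.7 CPM in URE het Tet2 KO replicate 2. Male Normal libraries ran from 68.3 to 84.5 CPM. Sex is not given per library, so it was not tested as an explanation.

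Among the features named enh, whose meaning is not given, 867 of 22241 tested differed between AML and Normal in edgeR, 629 higher and 238 lower, in data that the comparisons of genes leave out.

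Other splits of the same libraries show how often a result as large arises. For AML against Normal 2 of 100 splits gave as many genes as the real 2188, the real one included, in fits that ignore the title range. With the range as a term and splits drawn within each range, 2 of 100 reached the real 3664. Both shares lie under 0.05, which argues against chance for both counts but does not exclude it. The highest others, 3236 and 4256, came from splits with 4 of the 5 AML libraries on 1 side. Both kept URE het Tet2 het replicate 1 and URE het Tet2 KO replicates 2 and 3 together, as the real grouping does. With the range term, a split with 4 AML libraries that lacked URE het Tet2 het replicate 1 gave 2 genes. The shares therefore do not tell a difference of AML as a whole from a difference of those libraries. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real counts of 676, 195 and 71 genes for URE het Tet2 KO against WT, Tet2 KO and URE het were each reached by 1 of 10, with 0 in the highest other. A real count of 0 is reached by every split, so the 10 of 10 for URE het, Tet2 het and Tet2 KO against WT (highest other 0) and the 100 of 100 for the interaction of the URE deletion with Tet2 KO (highest other 4) decide nothing. Called gene lists were as many in 2, 3, 1, 1, 1 and 4 of 10 splits for URE het, Tet2 het, Tet2 KO and URE het Tet2 KO against WT, then URE het Tet2 KO against Tet2 KO and URE het, where the real numbers were 15, 8, 12, 18, 15 and 11 and the highest others 17, 10, 11, 10, 12 and 16. For lists, chance is not excluded in AML against Normal (19 of 100 splits reached the real 13, highest other 19, and 18 of 100 the real 14 with the range term, highest other 18) nor in the interaction with Tet2 KO (37 of 100 reached the real 10, highest other 19), so the preset camera calls are weak evidence here.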

How the results depend on the processing

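Fits within each range of title numbers, of the Normal libraries alone, and without the 2 libraries that had neither Xist nor Y-linked transcripts were chosen after the data were seen. Counts below are of called genes, in the order used in the report unless the comparison is named; where a count moved, the cause was not tested, except that fits with fewer libraries estimate the spread from fewer of them. DESeq2 size factors and non-robust edgeR kept every count within 1.5 times of the main one. Among named genes, the direction and side of the threshold held in 235 of 239 results with DESeq2, 201 of 239 with voom, 181 of 239 without the filter, 184 of 238 without the 2 libraries that had neither transcript, and 114 of 238 with the sex term, whose fit leaves out those 2 libraries as well. It held in fewer still with only the compared groups in the fit (60 of 151) and without URE het Tet2 KO replicate 2 (78 of 224) or 3 (81 of 225). Depth limits the rarest genes, such as those with 0 counts in a group.

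With DESeq2 the counts were 7 for URE het, 1 for Tet2 het, 12 for Tet2 KO, 695 for URE het Tet2 het and 1864 for URE het Tet2 KO against WT. They were 599 and 1212 for the compounds against Tet2 het and Tet2 KO, 530 and 1013 against URE het, 335 between the compounds, 103 and 151 for the interactions, and 242 genes in both compound comparisons. With voom URE het and Tet2 KO against WT gave 79 and 86, URE het Tet2 KO gave 5245, 3649 and 3385 against WT, Tet2 KO and URE het and 0 against URE het Tet2 het, and its interaction 1782. Without the filter URE het Tet2 het against WT and the interaction with Tet2 KO each gave 1, and the shared response had r = 0.359. With only the compared groups in the fit, URE het Tet2 KO gave 100 against WT, 23 against Tet2 KO, 15 against URE het and 0 against URE het Tet2 het; URE het Tet2 het gave 3 against URE het, and the interaction with Tet2 KO 32.

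With the term for title numbers URE het Tet2 het gave 176, 145 and 108 against WT, Tet2 het and URE het, and URE het Tet2 KO 1133, 415, 258 and 14 against WT, Tet2 KO, URE het and URE het Tet2 het; AML against Normal gave 3664 and both compound comparisons together 34. With the sex term, in a fit that also leaves out the 2 libraries with neither transcript, these were 64 and 56 (URE het Tet2 het against WT and Tet2 het), 448, 119, 27 and 406 for URE het Tet2 KO, and 45 for AML against Normal. In the Normal libraries alone with the title term, URE het against WT gave 16. Within title numbers 1 to 7 the counts were 41, 41 and 27 for the single genotypes, 3639, 3026 and 2420 for URE het Tet2 het, 1222, 402, 466 and 2744 for URE het Tet2 KO, 1804 and 192 for the interactions and 275 in both compound comparisons, with r = 0.281. Within 8 to 17 they were 10 for URE het against WT, 42, 838 and 1497 for URE het Tet2 het, 2789, 3512, 3752 and 4861 for URE het Tet2 KO, 48 and 723 for the interactions, 4307 for AML against Normal and 204 in both compound comparisons, with r = 0.183. Without the 2 libraries that had neither Xist nor Y-linked transcripts URE het Tet2 het gave 178, 122 and 142, URE het Tet2 KO 443, 220 and 536 against Tet2 KO, URE het and URE het Tet2 het, its interaction 35, AML against Normal 610 and both compound comparisons 1, with r = 0.161. Within 1 to 7 the spread rests on the 2 WT libraries and each mutant genotype has 1, so passing there carries no weight; in other fits where a group keeps 1 library, that library is assumed to vary like the other groups.

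Leaving out 1 library at a time kept 0 calls in the single genotypes. The range was 0 to 1172 for URE het Tet2 het against WT, 0 to 1219 against Tet2 het and 0 to 855 against URE het. It was 16 to 2521 for URE het Tet2 KO against WT, 3 to 1799 against Tet2 KO, 0 to 1789 against URE het and 1 to 1015 against URE het Tet2 het. The interactions ranged from 0 to 284 with Tet2 het and 0 to 279 with Tet2 KO, AML against Normal from 845 to 3998, the shared r from 0.188 to 0.664 and the genes in both from 0 to 112. The highest counts came without URE het Tet2 KO replicate 1 or URE het Tet2 het replicate 2 (URE het Tet2 het replicate 1 for the comparison of the compounds), and the lowest count of AML against Normal without URE het Tet2 het replicate 1.

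Of the gene lists called at the preset correlation, an estimated correlation left 1 in URE het against WT, 1 in URE het Tet2 KO against WT and 0 in the other 11 comparisons. With fry they numbered 1, 0 and 0 in the single genotypes, 2, 3 and 0 in URE het Tet2 het, 11, 9, 5 and 1 in URE het Tet2 KO, and 0 and 0 in the interactions.

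These values changed sign, and the cause was not tested. Spi1 in Tet2 het against WT was 0.15 with the title term, 0.08 in Normal libraries alone, and 0.11 and 0.04 within the ranges. Spi1 in Tet2 KO against WT was 0.20, 0.13, 0.25 and 0.05 in those fits, 0.07 with the sex term, and -0.71 to 0.08 with 1 library left out. Tet2 in URE het Tet2 KO against WT was -0.12 within 1 to 7 and -0.09 to 0.27 with 1 library left out, and Thy1 there was -0.80 within 1 to 7. Against URE het, Spi1 was 0.11 within 1 to 7 and Tet2 0.04 with voom, 0.05 with the sex term and -0.38 to 0.05 with 1 library left out. Spi1 in URE het Tet2 KO against URE het Tet2 het was -1.18 with voom, -0.11 with the title term, -1.80 within 8 to 17 and -1.49 to 1.01 with 1 library left out, and in the interaction with Tet2 KO -2.49 to 0.03. In AML against Normal, Lepr was -0.09 without the 2 libraries, and Trp53inp1 -0.32 with the sex term, -0.17 without the 2 libraries and -0.02 to 2.09 with 1 library left out.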

Other observations

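The test of chromosome 2 with ends that differ between libraries was chosen after the result was seen; the other tests of this part were chosen before.

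Oxidative phosphorylation genes differed between the 2 compound genotypes at the preset correlation and not at an estimated one. In URE het Tet2 KO against URE het Tet2 het, 29 of 31 members were higher (median log2 fold change 0.63, camera adjusted p = 2.34e-15, and 0.131 with an estimated correlation), and 13 passed as higher adjusted over the list alone, while none passed among all genes. The same list was higher in the later range of title numbers (median 0.32, adjusted p = 0.000629, and 0.951 with an estimated correlation), which holds 2 of the 3 URE het Tet2 KO and 1 of the 2 URE het Tet2 het libraries. In that range PU.1 target genes had a median of -0.65 relative to the earlier range (0.603 with an estimated correlation) and late neutrophil genes -0.85 (0.951 with an estimated correlation).

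A hypothesis from the data is that the cells of 3 AML libraries had lost 1 copy of a part of chromosome 2 that includes Spi1, so that the intact allele or the enhancer-deleted one was left alone. The first test asked for an unbroken run of 10 Mb windows below -0.6 in all 3 libraries: 9 of 19 windows were below it, all between 60 and 160 Mb, but the window from 100 to 110 Mb stood at -0.53 in URE het Tet2 KO replicate 2, so that test left it open. The second let the ends differ. It also used a cut-off less strict than -0.6, which the window at -0.53 passes. Since it was set after that result, it is not independent support for a loss. A scan of 244 windows per library found 1 run in each of the 3 libraries. The runs went from 60 to 160 Mb in URE het Tet2 het replicate 1, 50 to 160 Mb in URE het Tet2 KO replicate 2 and 60 to 170 Mb in URE het Tet2 KO replicate 3. There were 0 runs in the 12 Normal libraries, in URE het Tet2 KO replicate 1 or in URE het Tet2 het replicate 2. The medians of the 3 runs were -0.89, -0.91 and -0.88 in that order. A loss of 1 copy in most cells predicts about -1, and these values are consistent with it. RNA cannot tell a loss of DNA from lower expression along the stretch, nor which allele is left. Spi1 itself stood at 7.83 to 21.6 CPM in those libraries, further below the Normal mean of 80.4 ± 33.4 CPM (SD, n = 12) than the stretch as a whole.

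Kdm6a, an X-linked histone demethylase (chromosome X, 18162575 to 18279936), had 21 counts (0.683 CPM) in URE het Tet2 het replicate 1 against 45.7 to 142 CPM in the other 16 libraries. The lowest of those, at 45.7 CPM, was URE het Tet2 KO replicate 2, the other library with neither Xist nor Y-linked transcripts. A deletion across the tested neighbours is argued against. The 10 tested neighbours within 2 Mb on each side had a median ratio of 0.973 to the other libraries. None of them lies between Fundc1, which ends at 17572325, and Mir221, which starts at 19146294. A loss within that gap, or silencing of Kdm6a, may still be the reason and was not tested. Among the 10 neighbours, 4 lay at or below 0.143. Of those 4, 3 were below 1 CPM in the other libraries as well, and Slc9a7 had 0 CPM where the median of the others was 4.44.

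Tet2 KO replicate 1 had 0.269 CPM of the Y-linked gene Eif2s3y beside 22.7 CPM of Uty and 40.9 CPM of Kdm5d. Of 867 enh features that differed between AML and Normal, 703 had a host gene with a test; the host passed in the same direction for 356, in the opposite direction for 8 and did not pass for 339.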
